A study of Mus musculus with 9 samples.

How the data were processed

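The series measured small RNAs of mouse gonads by sequencing, in 9 samples of 1 library each. The total RNA samples held RNA selected at 24 to 33 nt, and the remaining samples held RNA recovered by immunoprecipitation of the PIWI proteins MILI (gene Piwil2) or MIWI2. Reads of 6 samples were used here: MIWI2-bound RNA of testis at 16.5 days post coitum (dpc), total RNA of testis at 2 and 10 days post partum (dpp), the last from MILI-heterozygous animals, total RNA of MILI-deficient testis at 10 dpp, a library labelled 10 dpp MILI-bound from Dnmt3L-heterozygous testis, and a library labelled ovary total from females of 4 to 6 weeks. The MILI-bound sample of Dnmt3L-deficient testis and the total and MILI-bound samples at 16.5 dpc were not analysed here.

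Per the labels' protocols, the authors either size-selected total RNA or immunoprecipitated the PIWI complexes before cloning, and the other deposited values, in the read files, are untrimmed sequencer reads of 30 nt (MILI-deficient), 35 nt (labelled 10 dpp MILI-bound) or 36 nt (the other 4 libraries) that still carry the cloning linker. Per the file headers, the authors' table of the whole series lists each distinct sequence with its number of genomic matches and a genomic annotation, and holds no read counts. The aligner, the genome build and the order in which annotations were chosen are not given in the sources used here. The sign in the annotation was checked against GENCODE transcripts and followed the strand of the annotated feature, not that of the read. The table listed 5043644 sequences, of which 98.0% were 24 to 33 nt long, 71.3% had 1 genomic match, and 1593455 (31.6%) occurred in none of the 6 libraries.

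The linker CTGTAGGCACCATCAATC was read from the data. An insert ended at an exact match to 8 linker bases, or, near the end of a read, to all the linker bases left if these were at least 3. The rule fixed before the data were examined asked for 8 linker bases in every read, which allows no insert above 28 nt in 36-nt reads or above 22 nt in 30-nt reads, and it is given as an alternative. Inserts of 24 to 33 nt that the authors' table lists were counted, and every share has these reads as its denominator unless another is named. Each sequence carries 1 annotation in the table, which set its class and its repeat name or gene. RefSeq identifiers were turned into symbols for 16058 of 16455 identifiers with the reference annotation, which served only for names, chromosomes and transcript sequences; no positions are given, since the build of the table is not stated. The main ratios of the MILI-deficient to the heterozygous library had both cut to 30-nt reads and inserts of 24 to 27 nt. Longer inserts cannot be seen in the reads of the deficient library. Lengths, base marks, class shares, exon regions, strand, overlaps and sharing were not matched in this way. There, inserts above 27 nt entered for the other libraries only.

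Sequencing gave 4046183 reads for the MIWI2-bound library, 4613567 for 2 dpp total, 3845266 for 10 dpp total, 1436951 for the MILI-deficient library, 2687443 for the library labelled 10 dpp MILI-bound and 2496323 for the library labelled ovary total. No linker was found in 54.3%, 61.4%, 35.8%, 71.6%, 37.8% and 88.0% of these reads, in the same order. Base qualities ran from -5 to 40 in 4 libraries, where their mean lay under 20 in 89.2% of reads at 2 dpp, against 12.4% in the MIWI2-bound library, 7.44% at 10 dpp and 11.0% in the library labelled ovary total. They ran from -5 to 27 in the library labelled 10 dpp MILI-bound, with 99.9% of reads under 20, and from 1 to 30 in the MILI-deficient library, with 3.28% under 20 and 70.3% at 30 in every base. Whether these 2 libraries share the scale of the others is not known. Of inserts of 24 to 33 nt, 67.2%, 69.6%, 74.9%, 33.6%, 71.6% and 37.6% were listed in the table.

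Strand was measured from sequence, because no genome was used here. Listed sequences of L1Md, IAPEz-int and MMERGLN-int were assembled into contigs of at least 300 nt (words of 20 bases), each contig with a reading frame of at least 140 amino acids was oriented by its longest frame, and reads were placed with at most 3 mismatches; 7 families had been tried and these 3 were kept after their contigs were seen. Ping-pong partners, in which 2 PIWI proteins cut opposite strands and leave 5′ ends that overlap by 10 nt, were searched by sequence. A read had a partner at a given overlap when the 5′ end of a listed read of the same library lay at that distance on the opposite strand, with the upstream bases bridged by another listed sequence, so overlaps of 5 to 14 nt were measured instead of the planned 5 to 20. Overlap shares have as denominator only the reads whose upstream bases were bridged. Exon reads were oriented and assigned to untranslated or coding regions with GENCODE transcripts of the same gene. Sharing was measured after thinning 2 libraries to 81753 reads each, as the percent of the distinct sequences of the library with fewer of them that also occurred in the other.

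Groups were taken from the labels. With 1 library per group no test between groups was made, and ratios compare libraries and not conditions. Shares have exact Clopper-Pearson intervals and ratios of shares exact conditional binomial intervals, both at 95%, from SciPy 1.17.1 under Python 3.11.15 with NumPy 2.4.6; Matplotlib 3.10.9 drew the figures. Intervals cover counting error only. A ratio was called higher or lower at 2-fold or more with an interval that excluded 1, and values between 0.5 and 2 are given without a direction. A count of 0 was taken to allow up to 3 counts. Units with at least 100 reads in 1 of the 2 libraries, structural RNAs left out, were compared. The units named follow a rule fixed before the data were examined, which took the 10 largest ratios in each direction, the 10 most-read units of each library, and fixed lists: young L1 (L1Md, L1_Mm and L1_Mus names), old L1 (other L1 and Lx names), IAP, ETn/MusD, MERVL, MaLR, other ERVK, ERV1, the SINE families B1, B2, B4, ID and MIR, LINE2, DNA transposons and satellites. MMETn-int was placed with ETn/MusD, ties were broken and the 5 most-read genes of each library were added after the data were seen. The marker genes Nanos2 and Dnmt3l, the Y-linked genes and the exon lists of ovary and oocyte genes and of fetal testis genes were also chosen then. The fixed miRNA lists covered primordial germ cells together with pluripotent cells (mir-17, mir-18a and mir-20a among the members), meiotic germ cells, gonadal soma (with every let-7 miRNA), blood, muscle, liver, brain and endothelium.

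On simulated reads without errors that all held at least 3 linker bases, trimming returned the true length of at least 99.96% of inserts. Reads without a linker were not simulated, so chance matches of 3 bases at a read end were not measured. In simulated counts, the comparison of the MILI-deficient library called 97.9% of units raised 3-fold, 68% of units lowered to 1/3 and 90% of units lowered to 1/6, and it called 1.06% of unchanged units. The comparisons of 10 dpp with 2 dpp, of the MIWI2-bound library with the library labelled 10 dpp MILI-bound and of the latter with 10 dpp total called 100% of changed and 0% of unchanged units. That of the library labelled ovary total with 10 dpp total called 100% of units raised 3-fold, 69.4% of units lowered to 1/3, 93.75% of units lowered to 1/6 and 1.20% of unchanged units. In each comparison both simulated libraries were drawn from the counts of 1 library with counting error only. These shares hold no spread between libraries and are not error rates of the real comparisons. The overlap search found partners at 10 nt for 32.5% of simulated reads where 30.6% had been made with one, and the strand search returned 70.3% antisense where 70% had been simulated.

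The alternatives counted distinct sequences, left out sequences read in a single copy or the 10 most abundant, took inserts of 24 to 30 nt or from 18 nt, matched 6 or 10 linker bases or left out reads of mean quality under 20 (these 3 for the mean MIWI2-bound length), or changed the denominator. Distinct sequences and sequences read in a single copy were found at the full depth of each library, which differed between libraries. Both alternatives therefore also change with depth. Those chosen after seeing the data required 8 linker bases in every read or at least 5 at its end, allowed 1 mismatch in 4 linker bases, joined the first 24 nt of every read to the first 24 nt of the listed sequences without trimming, exchanged the partner library, left out reads of mean quality under 20 from the comparison of 10 with 2 dpp and from no other comparison, added denominators to those planned for a comparison, allowed no mismatch or only 1 genomic match for strand, or thinned the repeat reads for the overlaps.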

Results

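Small RNAs of mouse testis and ovary were sequenced to follow piRNAs, the 24 to 33 nt RNAs that PIWI proteins carry and that direct the silencing of transposons in germ cells. Of 9 samples, 6 were analysed, each the only library of its group: MIWI2-bound RNA at 16.5 dpc, total RNA at 2 dpp, total RNA of MILI-heterozygous and of MILI-deficient testis at 10 dpp, a library labelled 10 dpp MILI-bound from Dnmt3L-heterozygous animals, and a library labelled ovary total. No group had a replicate, so no test between groups was made, and the 95% intervals given cover counting error only. Listed inserts of 24 to 33 nt numbered 1194724 in the MIWI2-bound library, 852127 at 2 dpp, 1655569 at 10 dpp, 81753 in the MILI-deficient library, 1014659 in the library labelled 10 dpp MILI-bound and 88680 in the library labelled ovary total. A count of 0 allowed up to 2.51, 3.52, 1.81, 36.7, 2.96 and 33.8 reads per 1000000 in the same order.

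Some contents of the library labelled 10 dpp MILI-bound and of the library labelled ovary total left their labels in doubt without settling them. Repeat shares of the library labelled 10 dpp MILI-bound correlated across 179 repeat names, which are not independent replicates, at r = 0.964 with the MIWI2-bound library and at 0.632 with 10 dpp total. With the first 24 nt of every read, the library labelled ovary total held 6 reads assigned to the Y-linked genes Usp9y and Eif2s3y. Their 1 genomic match is that of a listed sequence with these first 24 nt, so X-linked copies may be included. After trimming 1 read of Y-linked genes remained, below the limit that a count of 0 allows. With the first 24 nt, Nanos2, a gene of male germ cells, stood at 130.4 per 1000000 reads against 9.70 in 10 dpp total. It also stood at 6.63 at 2 dpp and 0 in the MILI-deficient library, so its small RNA reads do not mark testis as such. Comparisons with these libraries keep the labels' names and are given as the labels state them.

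Small RNAs bound by MIWI2 were the longest, with a mean of 28.2 nt and 70.04% of reads at 28 nt or more. Total RNA had means of 26.6 nt at 2 dpp and 26.8 nt at 10 dpp, with commonest lengths of 26 and 27 nt. The library labelled 10 dpp MILI-bound had a mean of 27.3 nt and 44.7% of reads at 28 nt or more, and the library labelled ovary total had a mean of 26.5 nt. Reads of the MILI-deficient library could show at most 27 nt, which was its commonest length.

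**Figure D1:**
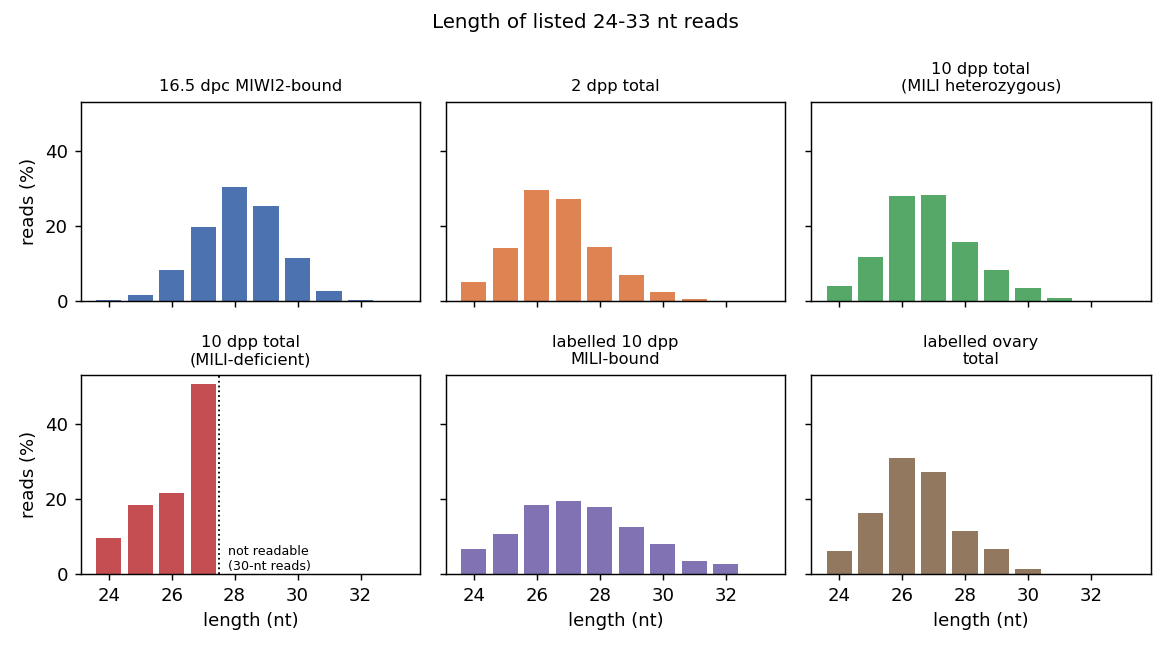
Share of listed reads (percent) at each insert length (nt), 1 panel of bars per library. The MIWI2-bound library peaked at 28 nt and the total testis libraries at 26 and 27 nt, and the dotted line marks 27 nt, the longest insert that the 30-nt reads of the MILI-deficient library can show.

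A uridine at the 5′ end, the mark of primary piRNAs, opened 72.02% of MIWI2-bound reads, 76.9% at 2 dpp, 84.5% at 10 dpp, 71.6% in the library labelled 10 dpp MILI-bound and 82.4% in the library labelled ovary total, but 40.7% in the MILI-deficient library. Among repeat reads alone the MILI-deficient library had 71.6%, beside 71.2% in the MIWI2-bound library, 73.0% at 2 dpp, 83.0% at 10 dpp, 77.4% in the library labelled 10 dpp MILI-bound and 80.4% in the library labelled ovary total. Adenine at position 10, the mark left on the partner strand of ping-pong cleavage, was present in 65.6% of MIWI2-bound reads without a 5′ uridine. The same share was 35.2% at 2 dpp, 36.8% at 10 dpp, 21.8% in the MILI-deficient library, 35.8% in the library labelled 10 dpp MILI-bound and 46.6% in the library labelled ovary total. Among repeat reads alone it was 68.9%, 49.3%, 46.9%, 56.7%, 62.7% and 53.3% for the MIWI2-bound, 2 dpp, 10 dpp, MILI-deficient, labelled 10 dpp MILI-bound and labelled ovary total libraries.

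LTR retrotransposons, the class that includes the IAP elements, supplied 47.4% of MIWI2-bound reads, 14.2% at 2 dpp and 30.9% at 10 dpp. LINE reads, which come mostly from L1, made up 28.1%, 7.02% and 9.83%, and SINE reads 6.03%, 20.7% and 12.9% in the same libraries. Gene exons gave 23.7% of reads at 2 dpp and 18.1% at 10 dpp but 1.26% of MIWI2-bound reads. The library labelled 10 dpp MILI-bound held 29.8% LTR, 19.2% LINE, 5.72% SINE and 2.88% exon reads, and the library labelled ovary total held 30.3%, 22.6%, 7.58% and 5.31%. Fragments of structural RNAs took 37.9% of the MILI-deficient library and 13.8% of the library labelled 10 dpp MILI-bound, with miRNAs at 16.1% and 5.40%, and they took 3.03% or less of the other 4. With the first 24 nt of every read, structural RNAs took 75.7% and miRNAs 8.53% of the MILI-deficient library, where transfer RNAs took 62.1%, against 14.9% after trimming.

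**Figure D2:**
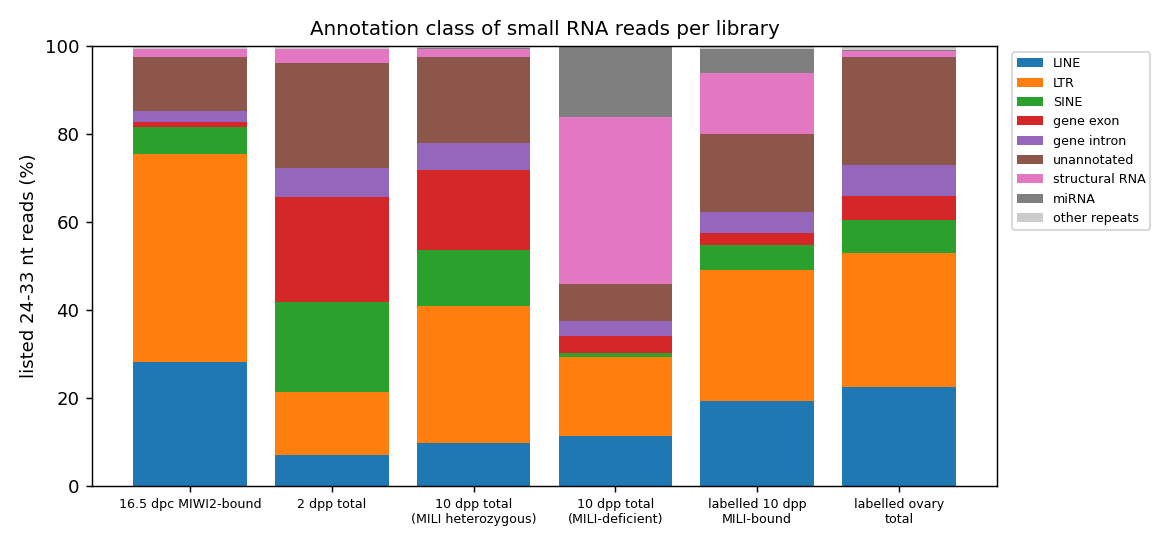
Share of listed reads (percent) in each annotation class for the 6 libraries, 1 stacked bar per library. LTR reads lead in the MIWI2-bound library (47.4%), and structural RNA and miRNA reads fill 37.9% and 16.1% of the MILI-deficient library after trimming (75.7% and 8.53% with the first 24 nt of every read).

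The MILI-deficient and MILI-heterozygous testes at 10 dpp address which small RNAs need MILI, the PIWI protein of prospermatogonia and later germ cells that the gene Piwil2 encodes. Piwil2 itself gave 44 reads in the heterozygous library (26.6 per 1000000 reads) and 0 in the deficient library, which allows up to 36.7 per 1000000 reads and so did not show a difference at this depth. The other libraries had 3 trimmed Piwil2 reads (MIWI2-bound), 42 (2 dpp), 16 (labelled 10 dpp MILI-bound) and 1 (labelled ovary total). With untrimmed reads matched by their first 24 nt, Piwil2 had 58 reads in the heterozygous library (25.6 per 1000000 reads) and 0 in the deficient library, which allows up to 3.94 per 1000000 reads. Structural RNA and miRNA reads made up most of the deficient library in this setting. The limit over its other reads is therefore higher, and a difference in Piwil2 is not shown. The other libraries then had 5, 102, 21 and 10 reads in the order above.

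Small RNAs of SINEs and of genes took far lower shares of the MILI-deficient library than of the heterozygous library. Structural RNAs and miRNAs took more of the deficient library, which lowers every other share of its listed reads. Counts of lower names and genes were made over all listed reads only. B1 elements were 15.1-fold and B2 elements 14.2-fold lower in the deficient library, with all 14 B1 and all 5 B2 names lower, among them B1_Mus1 (18.5-fold) and B2_Mm1a (49.1-fold, interval 30.6 to 84.3). All 4 B4 names and all 4 ID names were lower as well, the B4 list by 6.46-fold and the ID list by 7.78-fold, although the ID list fell by 0.29 on the log2 scale with the first 24 nt of every read. Small RNAs of genes were lower for 587 of 627 genes: Abl2, a tyrosine kinase gene, had 5 reads against 4891 (55.9-fold lower), Fth1, the ferritin heavy chain gene, had 5 against 2560 (29.2-fold lower), and Tmed8 had 0 against 1992 (at least 37.9-fold lower). Cbx5, which encodes heterochromatin protein HP1α, had 2 reads against 3278, a ratio of 0.0107 (interval 0.00129 to 0.0386).

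IAP elements, active endogenous retroviruses, took 4.43% of reads in the deficient library and 20.7% in the heterozygous library, 4.68-fold lower, but the direction turned over distinct sequences (log2 ratio 0.55). Of 14 IAP names, 10 were lower, 1 was higher and 3 lay between, and IAPEz-int, the internal part of IAP, was 4.83-fold lower and turned as well (log2 ratio 0.69). Distinct sequences were counted without matching depth. IAPEz-int had 1185 over 2923 reads in the deficient and 21430 over 247032 reads in the heterozygous library. These turns therefore cannot be told apart from an effect of depth. The related MMERVK10C-int was 12.2-fold lower (interval 10.4 to 14.4). Over repeat reads alone the differences were smaller. IAPEz-int took 11.8% of these in the deficient and 32.3% in the heterozygous library, and MMERVK10C-int 0.615% and 4.27%. Young L1 took 10.2% of reads against 7.52%, a ratio of 1.36, with 1 of its 11 names higher and 10 between, including L1Md_F2 at 1.56, L1Md_T at 1.12 and L1Md_A at 0.982. Old L1 had a ratio of 0.526, with 20 of 35 names lower and 15 between. ETn/MusD elements had a ratio of 0.919 and all 5 names between.

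These 3 lists had no direction that held across the processing. Their values over distinct sequences also depend on depth, which was not matched. Young L1 was more than 2-fold higher over reads other than structural RNA and miRNA (log2 ratio 1.53), over repeat reads (1.25) and over distinct sequences (1.35), but lower with at least 5 linker bases at the read end (-1.80), with the first 24 nt of every read (-1.29), per miRNA read (-7.06) and per structural RNA read (-3.67). L1Md_F2, L1Md_T and L1Md_A likewise stood at 1.41, 1.30 and 1.11 over distinct sequences and at -1.20, -1.70 and -1.68 with the first 24 nt. Old L1 passed 1 over reads other than structural RNA and miRNA (0.16) and was more than 2-fold lower without sequences read in a single copy (-1.005), from 18 nt (-1.10), over annotated reads (-1.12), with the first 24 nt (-2.03), with 5 linker bases (-2.74), per miRNA read (-8.43) and per structural RNA read (-5.04). ETn/MusD elements stood at 0.86 over distinct sequences, 0.97 over reads other than structural RNA and miRNA, 0.69 over repeat reads and 0.25 without the 10 most abundant sequences, but at -1.72 with the first 24 nt, -2.65 with 5 linker bases, -7.62 per miRNA read and -4.23 per structural RNA read.

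Against this, RLTR10-int, the internal part of an ERVK element, took 5.97% of reads in the deficient library and 0.448% in the heterozygous library, 13.3-fold higher (interval 12.8 to 13.8), although its log2 ratio turned to -3.77 per miRNA read and -0.38 per structural RNA read. Its long terminal repeat RLTR10 was 9.51-fold higher, with log2 ratios of -4.25 and -0.86 on those scales. MTA_Mm of the MaLR list (3.33-fold), MuRRS-int of the ERV1 list (3.66-fold) and L1_Mus2 (2.30-fold) were higher among listed reads but lower per miRNA read and per structural RNA read. The other ERVK list took 8.23% against 4.46%, a ratio of 1.84, with 6 of 47 names higher and 27 lower. Its log2 ratio was 1.73 over distinct sequences, 1.97 over reads other than structural RNA and miRNA, 1.70 over repeat reads and 1.25 without the 10 most abundant sequences, but -1.10 with 5 linker bases, -6.62 per miRNA read and -3.23 per structural RNA read. Of 627 genes 4 were higher: reads of Chd3, a chromatin remodeller gene, numbered 241 against 16 (264-fold, interval 159 to 469), and had a log2 ratio of 0.54 per miRNA read. Reads of the ribosomal protein genes Rps3 (3.57-fold) and Rps12 (3.34-fold) and of Sfmbt2 (2.69-fold), the last named after its values were seen, were higher but turned lower per miRNA read and per structural RNA read. Reads of all 4 genes lay in introns in the deficient library, but in the heterozygous library the intron share was 50% for Chd3, 0% for Rps3, 1.12% for Rps12 and 19.2% for Sfmbt2.

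Reads of the piRNA type, which begin with U and match repeats or genes, made up 24.0% of the deficient library and 66.2% of the heterozygous library, a log2 ratio of -1.46, which fell under 2-fold over distinct sequences (-0.50) and moved to -3.05 with the first 24 nt of every read, -3.50 with 5 linker bases, -5.58 per structural RNA read and -8.96 per miRNA read. With the first 24 nt the other ERVK list had a log2 ratio of -0.89 (against 0.88), and IAP was 14.7-fold lower. Small RNA reads of Piwil2 do not measure its messenger RNA and cannot settle the genotype of the library, whose read file carries WT in its name against a label of MILI deficiency. The label was followed, and every value of the MILI-deficient library rests on it.

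The age comparison of total RNA addresses how the piRNA population shifts between 2 and 10 dpp, with the 10 dpp animals heterozygous for MILI. Mean base quality lay under 20 in 89.2% of reads at 2 dpp and in 7.44% at 10 dpp. Small RNAs of several LTR retrotransposons took larger shares at 10 dpp. IAP elements took 21.0% of reads at 10 dpp and 6.40% at 2 dpp, 3.28-fold higher, although the ratio stayed under 2-fold over distinct sequences (log2 ratio 0.59, and 1.69 without reads of mean quality under 20). Of 14 IAP names 3 were higher and 11 lay between, with IAPEz-int at 4.04-fold (interval 3.99 to 4.08) and IAPLTR1a_Mm at 4.26-fold, both under 2-fold over distinct sequences (log2 ratios 0.79 and 0.14). MMERVK10C-int was 3.16-fold higher, and 7 of the 54 other ERVK names were higher. ETn/MusD elements were 2.68-fold higher, with 4 of 5 names higher and MMETn-int at 4.87-fold. MMERGLN-int, which is outside the ERV1 list used here, was 5.56-fold higher (interval 4.98 to 6.22). Of 16 names in the ERV1 list, 14 lay between.

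Young L1 had a ratio of 1.53 between 10 and 2 dpp, with 3 of 11 names higher, among them L1Md_Gf (4.56-fold) and L1Md_T (2.27-fold, log2 ratio 0.85 over distinct sequences), and L1Md_A at 1.97 (log2 ratio 1.14 with the first 24 nt of every read). Old L1 names stayed between in 33 of 36 cases. B1 elements took 6.49% at 10 dpp and 12.3% at 2 dpp, a ratio of 0.527, and 3 of 14 names were lower, B1_Mus1 by 2.09-fold, B1_Mus2 by 2.16-fold and B1_Mm by 2.09-fold. These 3 calls ended over distinct sequences (log2 ratios -0.64, -0.64 and -0.66) and without reads of mean quality under 20 (-0.30, -0.51 and -0.57), and those of B1_Mus1 and B1_Mus2 without the 10 most abundant sequences (-0.94 and -0.77). The B1 list passed 2-fold with the first 24 nt of every read (log2 ratio -1.16), over repeat reads (-1.27), without sequences read in a single copy (-1.29) and with linker mismatches (-1.07), but stood at -0.44 without reads of mean quality under 20. All 5 B2 and all 4 B4 names lay between, as did all 7 MERVL names. Among 736 genes, 37 were higher at 10 dpp, 78 were lower and 621 lay between. Nrros had 272 reads against 0 (at least 46.7-fold higher) and Ky, a muscle gene, 510 against 10 (26.2-fold, interval 14.2 to 55.1, and a log2 ratio of 3.62 without reads of mean quality under 20), while Acsl3, a fatty acid activating enzyme, was 5.15-fold lower and Slc7a1, an amino acid transporter, 4.42-fold lower. The most-read genes moved less, with ratios of 0.645 for Abl2, 0.778 for Cbx5 and 1.35 for Fth1.

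The MIWI2-bound library and the library labelled 10 dpp MILI-bound address how the cargo of the nuclear protein MIWI2 and the cytoplasmic protein MILI differ. The labels put 16.5 dpc against 10 dpp, so age and protein differ together, and the label of the second library is in doubt. Their repeat shares were close: of 308 repeat names, 279 lay between, 16 were higher in the MIWI2-bound library and 13 lower. ETn/MusD elements took 4.70% against 1.97%, 2.38-fold higher, with 3 of 5 names higher and MMETn-int at 2.80-fold. The ETn/MusD ratio fell under 2-fold over distinct sequences (log2 ratio 0.84), over reads other than structural RNA and miRNA (0.97) and over repeat reads (0.68). IAP elements took 16.3% against 8.64%, a ratio of 1.89, with 5 of 16 names higher and IAPEz-int at 2.05-fold. The IAP ratio passed 2-fold without sequences read in a single copy (log2 ratio 1.0099), from 18 nt (1.12) and with the first 24 nt (1.005). RLTR4_MM-int (2.22-fold) was among 3 of 22 ERV1 names that were higher, and MMERGLN-int, outside that list, was 2.23-fold higher. All 11 young L1 names lay between, with L1Md_F2 at 1.64, L1Md_T at 1.46 and L1Md_A at 1.13.

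The calls for IAPEz-int, MMERGLN-int and RLTR4_MM-int ended over distinct sequences (log2 ratios 0.66, 0.61 and 0.64) and over reads other than structural RNA and miRNA (0.76, 0.88 and 0.87). That for IAPEz-int also ended without the 10 most abundant sequences (0.92), at 24 to 30 nt (0.981) and with 5 linker bases (0.984). Of 61 genes, 22 were lower in the MIWI2-bound library, 1 was higher and 38 lay between. Abl2 was 5.66-fold lower, with 47 reads against 226, and Cbx5 was 3.70-fold lower. Cbx7, a Polycomb gene, was 3.36-fold and Dnmt3a, a de novo DNA methyltransferase gene, 2.93-fold lower. The gene that was higher, Tatdn1, was 3.26-fold higher and its reads were 99.3% intronic in the MIWI2-bound library, but it stayed under 2-fold over distinct sequences (log2 ratio 0.96). Reads of Skap1, an adaptor protein gene, had a ratio of 1.27.

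**Figure D3:**
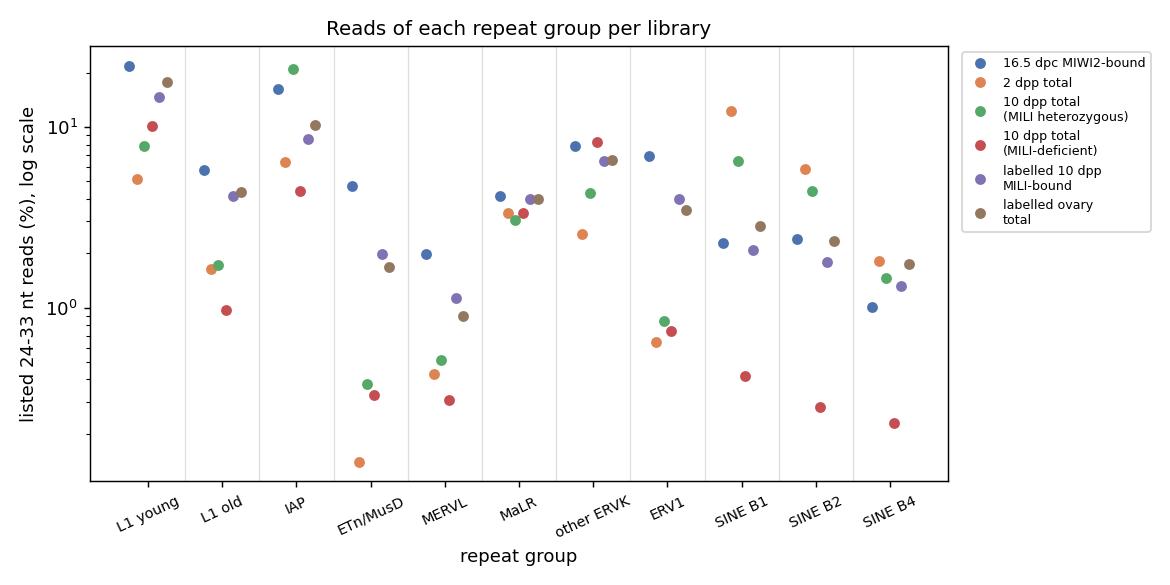
Share of listed reads (percent, log scale) from each repeat group, 1 point per library. IAP lies at 21.0% at 10 dpp and 6.40% at 2 dpp, and young L1 at 21.9% in the MIWI2-bound library.

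The library labelled 10 dpp MILI-bound set beside 10 dpp total RNA addresses what the immunoprecipitation holds of the total population, with Dnmt3L-heterozygous animals in the first and MILI-heterozygous animals in the second. The first label is in doubt, and each direction below is between the libraries as labelled. Small RNAs of genes were lower in the library labelled 10 dpp MILI-bound for 666 of 749 genes, and exon reads took 2.88% against 18.1%, a log2 ratio of -2.65 that moved to -4.56 without sequences read in a single copy. Depth was not matched in that alternative. Exon reads numbered 29243 over 27653 distinct sequences in the library labelled 10 dpp MILI-bound and 300171 over 198910 in 10 dpp total. Abl2 was 14.7-fold, Cbx5 12.3-fold, Hic2, a transcriptional repressor gene, 42.5-fold and Fth1 33.1-fold lower. Spry4 and Dusp6, inhibitors of growth factor signalling, had 0 reads against 309 (at least 63.1-fold lower) and 0 against 164 (at least 33.5-fold lower).

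ETn/MusD elements were 5.24-fold and ERV1 elements 4.72-fold higher in the library labelled 10 dpp MILI-bound. All 5 ETn/MusD names, such as MMETn-int (6.65-fold), and 20 of 22 ERV1 names were higher. MMERGLN-int, outside the ERV1 list, was 6.03-fold higher. Old L1 was 2.41-fold higher with 21 of 41 names higher. Young L1 had a ratio of 1.86, with L1Md_A at 2.80-fold, L1Md_T at 2.16-fold and L1Md_F2 at 1.50, and it passed 2-fold over reads other than structural RNA and miRNA (log2 ratio 1.18) and without sequences read in a single copy (1.08), while the L1Md_T call ended from 18 nt (0.90). RLTR10-int was 2.39-fold higher. IAP elements were 2.43-fold lower as a list and IAPEz-int was 4.72-fold lower, while 10 of 16 IAP names were higher, and over distinct sequences the list turned to a log2 ratio of 0.23 and IAPEz-int fell under 2-fold (-0.66). Depth was not matched for distinct sequences. B1 elements were 3.10-fold lower (8 of 14 names, B1_Mus1 by 4.75-fold) and B2 elements 2.46-fold lower (3 of 5 names, B2_Mm1a by 7.19-fold), but under 2-fold over distinct sequences (log2 ratios -0.95 and -0.57).

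Among 749 genes, 36 were higher in the library labelled 10 dpp MILI-bound. Reads of Skap1, 99.6% of them intronic, numbered 770 against 19 (66.1-fold, interval 42.1 to 110.4) and reads of Pou2f2, a transcription factor gene of B cells, 195 against 4 (79.5-fold). Dntt, the terminal transferase of lymphocytes, had 208 reads against 2, a ratio of 169.7 (interval 46.4 to 1410.5). The library also held 13.8% structural RNA and 5.40% miRNA reads.

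The library labelled ovary total set beside 10 dpp testis total RNA addresses how female and male gonads differ in their small RNAs. By the labels age differs together with sex, 4 to 6 weeks against 10 dpp, and the testes were MILI-heterozygous. The first label is in doubt. Small RNAs of genes were lower in the library labelled ovary total for 527 of 718 genes, with 10 higher and 181 between, and exon reads took 5.31% against 18.1%, a log2 ratio of -1.77 that moved to -4.05 without sequences read in a single copy. Depth was not matched in that alternative. Exon reads of the library labelled ovary total numbered 4713 over 4646 distinct sequences, so few of them were left. Abl2 was 10.02-fold lower with 29 reads against 5424, Cbx5 was 7.89-fold and Hic2 14.5-fold lower, and Dcaf7 had 0 reads against 1106 (at least 19.7-fold lower). Fkbp6, a cochaperone gene of meiosis, had a ratio of 0.801 (interval 0.524 to 1.18).

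ETn/MusD elements were 4.44-fold and ERV1 elements 4.11-fold higher in the library labelled ovary total than in 10 dpp total, with all 5 ETn/MusD names and 15 of 16 ERV1 names higher. RLTR6-int of the ERV1 list was 10.97-fold higher, and MMERGLN-int, outside that list, was 4.18-fold higher. Young L1 was 2.26-fold higher, with 4 of 11 names higher, among them L1Md_A (4.11-fold), L1Md_F (4.51-fold) and L1Md_T (2.52-fold), and old L1 was 2.54-fold higher with 23 of 35 names higher. The young L1 call ended with inserts from 18 nt (log2 ratio 0.92) and over repeat reads (0.995), and the old L1 call over distinct sequences (0.94). IAP elements were 2.04-fold lower as a list, with IAPEz-int 4.81-fold lower, while 11 of 14 names, such as IAPEY3-int (4.04-fold), were higher. The IAP ratio turned over distinct sequences (log2 ratio 0.56) and fell under 2-fold with the first 24 nt of every read (-0.73), without sequences read in a single copy (-0.31) and without the 10 most abundant sequences (-0.98), and IAPEz-int fell under 2-fold over distinct sequences (-0.40). Neither distinct nor single-copy sequences were counted at matched depth, so these changes also depend on depth. B1 elements were 2.30-fold lower, with 3 of 14 names lower and B1_Mus1 at 3.76-fold, but under 2-fold over distinct sequences (-0.89). Set beside the MIWI2-bound library, 211 of 292 repeat names lay between.

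Strand was measured for L1, IAPEz-int and MMERGLN-int from contigs assembled out of the listed sequences, of which the L1 contig of 5907 nt carried a reading frame of 1300 amino acids. Young L1 here means L1Md names only, without the L1_Mm and L1_Mus names of the young L1 list. Antisense reads, which can guide the cleavage of transposon transcripts, made up 52.9% of placed young L1 reads in the MIWI2-bound library, 65.5% at 2 dpp, 39.1% at 10 dpp and 70.7% in the MILI-deficient library. The library labelled 10 dpp MILI-bound had 56.4% antisense L1 reads and the library labelled ovary total 7.15%, which was 0.858% without sequences read in a single copy. That alternative was not matched for depth, and the library labelled ovary total held 88680 reads over 77662 distinct sequences. Placed IAPEz-int reads were mostly sense, with 29.1% antisense in the MIWI2-bound library, 13.3% at 2 dpp, 2.12% at 10 dpp, 13.0% in the MILI-deficient library, 19.04% in the library labelled 10 dpp MILI-bound and 6.05% in the library labelled ovary total. MMERGLN-int reads were 56.0% antisense in the MIWI2-bound library and 7.01% at 10 dpp, with 9 reads at 2 dpp and 2 in the MILI-deficient library, too few for a share. In the MIWI2-bound library a 5′ uridine opened 66.4% of sense and 69.9% of antisense L1 reads. Between 55.6% and 74.5% of young L1 reads could be placed.

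**Figure D4:**
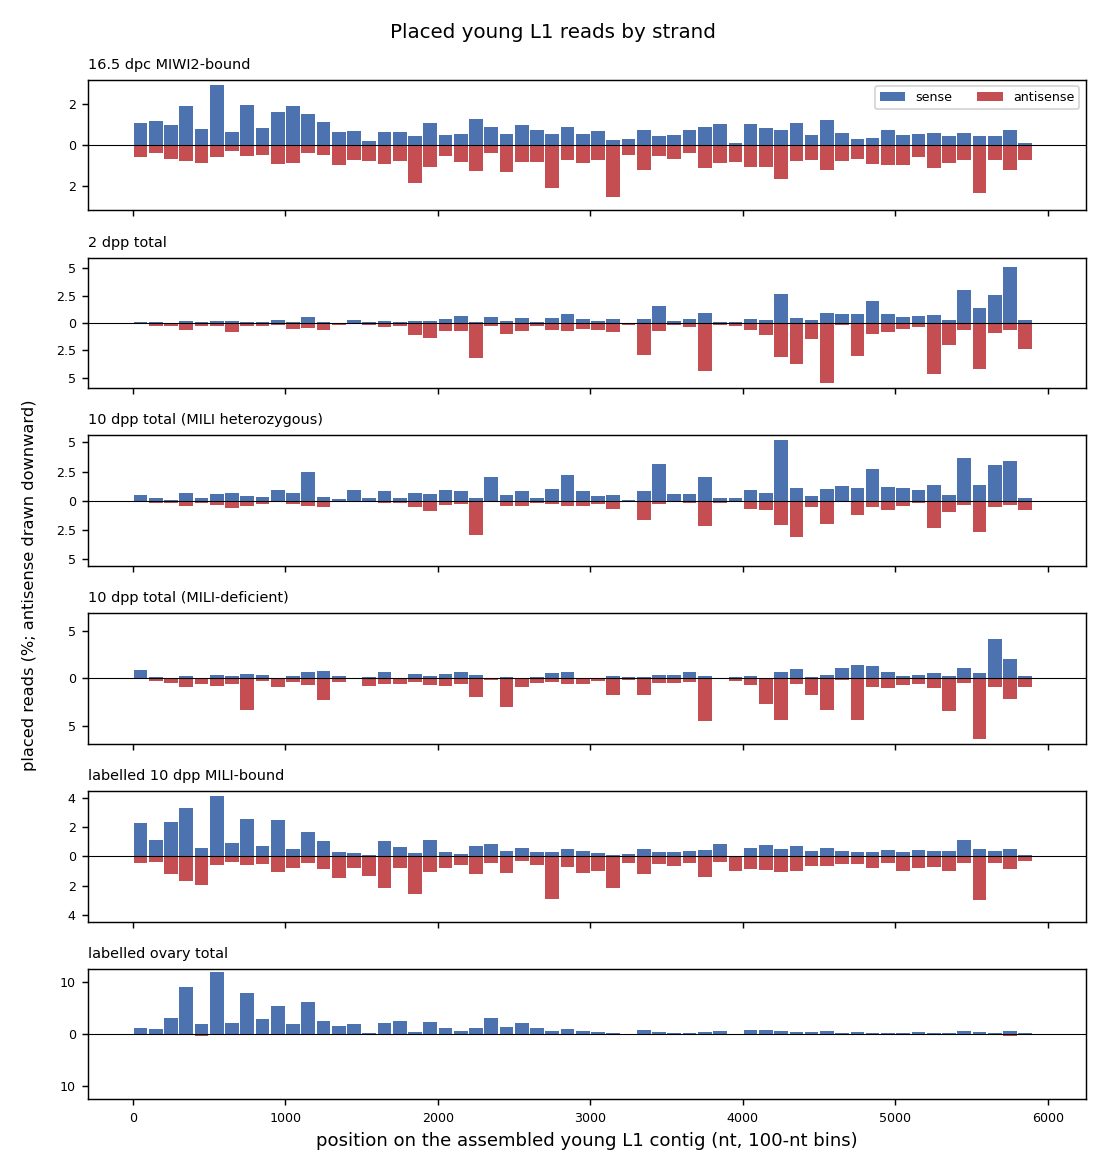
Share of placed young L1 reads (L1Md names only, percent) by position on the assembled L1 contig (nt), 1 panel per library, with sense reads drawn upward and antisense reads downward. Antisense reads sum to 7.15% in the library labelled ovary total and to 70.7% in the MILI-deficient library.

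Ping-pong partners, with 5′ ends that overlap by 10 nt, were counted for repeat reads whose upstream bases another listed sequence bridged. Every share below is of such bridged reads, not of all reads of the class. In the MIWI2-bound library 67.1% of bridged repeat reads had a partner at 10 nt against a mean of 43.1% at the other overlaps of 5 to 14 nt, a ratio of 1.56 that rose to 3.21 when every library was thinned to 24865 repeat reads. After that thinning the shares at 10 nt and at the other overlaps were 26.6% and 8.29% in the MIWI2-bound library, 33.4% and 20.7% at 2 dpp, 18.9% and 7.48% at 10 dpp, and 36.1% and 7.13% in the MILI-deficient library. These shares were 22.1% and 7.14% in the library labelled 10 dpp MILI-bound, and the library labelled ovary total 15.1% and 3.76%. In the MILI-deficient library the excess was present in LINE reads (39.3% against 5.93%) and LTR reads (35.03% against 7.99%), and SINE reads had 6.55% against 4.62%. With partners taken from another library, MIWI2-bound reads had 21.8% against 6.95% in the library labelled 10 dpp MILI-bound.

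**Figure D5:**
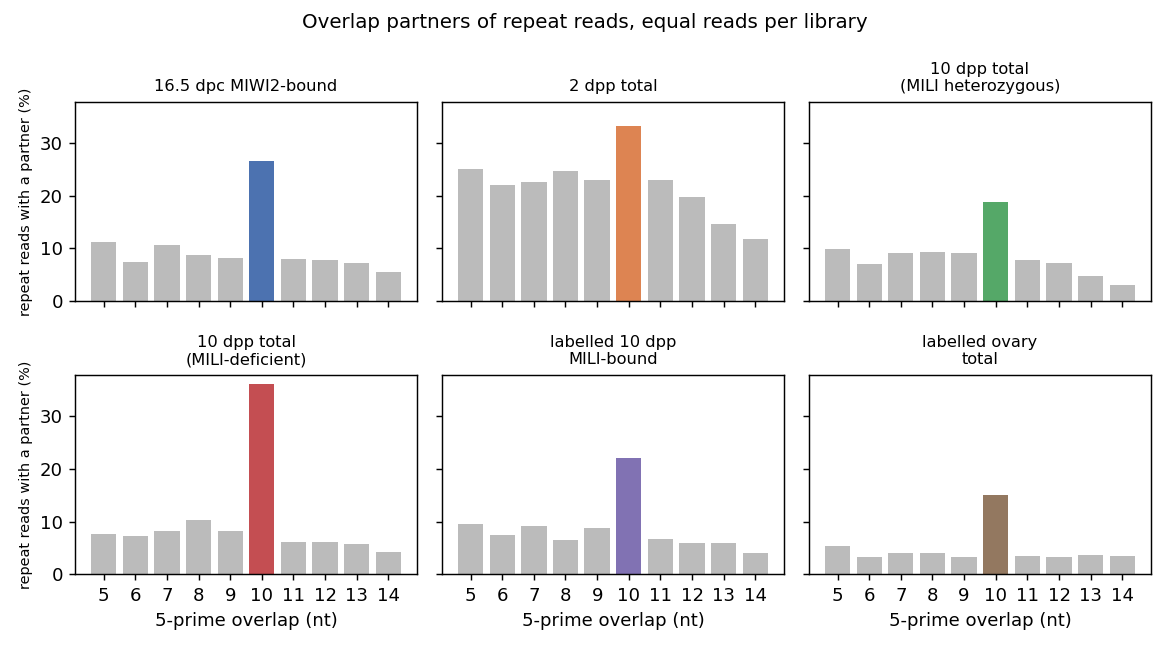
Share of repeat reads with bridged upstream bases (percent) that had a partner at each 5′ overlap (nt) after thinning to equal numbers of repeat reads, 1 panel of bars per library with 10 nt in colour. Every library has its highest share at 10 nt, 36.1% in the MILI-deficient library and 15.1% in the library labelled ovary total.

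At 81753 reads each, the 2 and 10 dpp total libraries shared 11.2% of distinct sequences, the MIWI2-bound library and the library labelled 10 dpp MILI-bound 7.63% (16.1% without sequences read in a single copy and 19.4% with the first 24 nt), and the MILI-deficient library and 10 dpp total 5.55%. Between the library labelled 10 dpp MILI-bound and 10 dpp total the shared part was 2.67%, and the library labelled ovary total shared 5.06% with the library labelled 10 dpp MILI-bound, 3.73% with the MIWI2-bound library and 3.22% with 10 dpp total. Among repeat sequences alone, the library labelled 10 dpp MILI-bound shared 11.1% with the MIWI2-bound library and 5.05% with 10 dpp total.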

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

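Tests chosen only after the result was seen were those of repeat selection and of a wrong label for the library labelled 10 dpp MILI-bound, all 3 tests for the library labelled ovary total, and those of carried-over reads, read length and MIWI2-bound sequences for the MILI-deficient library. Some were also revised after a first form. Repeat selection had been tested by structural RNA and miRNA reads (9.81 times those of 10 dpp total, taken as against it). It had also been tested by repeat sequences shared with 10 dpp total over those shared with the MIWI2-bound library. That ratio was 0.454 (interval 0.427 to 0.483), taken as against repeat selection but a restatement of the likeness. Carry-over and read length had been tested by the RLTR10-int share of repeat reads. That share was 8.44 times the highest other library and 23.4 times the heterozygous library, first taken as against both. A wrong label of the library labelled 10 dpp MILI-bound had been tested by its sharing with the MIWI2-bound library over that with 10 dpp total (2.86 times, interval 2.70 to 3.02, first taken as in line with it), which restates the likeness and cannot separate a wrong label from an immunoprecipitation that both libraries share. The bounds of the 3 tests of the library labelled ovary total were tightened after their values were seen, which left all 3 explanations open where carry-over and misread copies had first been argued against and a wrong label had been in line with the values.

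Signals in data outside the comparisons drew attention because they exceeded the limit that a count of 0 allows or, for short miRNAs, the count of 10 dpp total. The library labelled ovary total held 6 reads assigned to Y-linked genes when the first 24 nt were matched, and 1 after trimming. MURVY-int, a retrovirus named for the Y chromosome, reached 1136 reads per 1000000 for listed sequences with 1 genomic match (958.5 after trimming). Reads of 15 to 23 nt, shorter than the inserts compared here, included 148618 miRNA reads in the library labelled 10 dpp MILI-bound and 17434 in the library labelled ovary total. There were 2930 in 10 dpp total and 10087 in the MILI-deficient library, which was not screened by this rule. In the authors' table of the series, 1593455 listed sequences occurred in none of the 6 libraries.

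The library labelled 10 dpp MILI-bound differed from 10 dpp total RNA and resembled the MIWI2-bound library of 16.5 dpc. The values argued against a few abundant sequences, since over distinct sequences the correlation of repeat shares was 0.2495 higher with the MIWI2-bound library than with 10 dpp total, and against depth, since at equal depth it was 0.326 higher. A selection of repeats by the immunoprecipitation cannot be told apart from the rest: the correlation of repeat shares with 10 dpp total minus that of 2 draws of 10 dpp total was -0.342 (medians 0.613 and 0.956 at equal repeat reads), beyond counting error, but no 2 libraries of 1 group exist to give the spread between libraries. A wrong label cannot be told apart from a right one: the library shared 0.664 times as many distinct sequences with 2 dpp total as with 10 dpp total (interval 0.614 to 0.718), and the MIWI2-bound library, labelled 16.5 dpc, was also nearer to 10 dpp total (0.591 times, interval 0.549 to 0.637). The binding of a PIWI protein and the Dnmt3L genotype, which the labels name, stay open as untested.

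The library labelled ovary total held reads assigned to Y-linked sequences and resembled the MIWI2-bound library, with r = 0.899 across repeat names, and more so the library labelled 10 dpp MILI-bound, with r = 0.963 (0.871 and 0.9496 at equal depth). Reads carried over from a testis library, a wrong label and misread X-linked or autosomal copies could not be excluded and cannot be told apart. The rate of MURVY-int reads was 1.72 times the median of the libraries labelled testis (interval 1.60 to 1.85), but Y-linked genes stood at 1.58 times with an interval of 0.578 to 3.43, and their reads came from 2 genes, too few to decide whether copies elsewhere may have been misread as Y-linked. Ovary and oocyte marker genes in the library labelled testis that had most were 1.71 times those of the library labelled ovary total, which rests on 2 marker reads in the latter. Sex, tissue and age, which the labels name, stay open as untested.

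LINE and LTR reads remained in the MILI-deficient library. Carry-over from another library could not be decided. In the library that held most, 10 dpp total, 29.6% of these reads (interval 29.001 to 30.2) had a sequence with at least as many reads. In the same library 50.9% had a sequence that was found at all. A carried-over sequence need not be read again in its source at this depth, and the samples not analysed here were not searched. The values argued against degraded transcripts, since LINE partners at a 10-nt overlap were 5.23 times as frequent as at 9 and 11 nt. Read length could not be decided. LINE and LTR reads per SINE and exon read were 4.52 times those of the heterozygous library cut to the same length (interval 4.46 to 4.58). Cutting the heterozygous reads therefore did not give the same ratio. Both libraries were trimmed by the same linker rule, however, and chance linker matches at a read end were not measured. An effect of such matches in short reads stays open. Small RNAs of the population that MIWI2 binds cannot be told apart from others, since repeat sequences of the deficient library were found 0.877 times as often in the MIWI2-bound library as in 10 dpp total (interval 0.822 to 0.936), between the bounds set for either outcome. Loss of MILI itself, which the label names, may leave such reads and stays open as untested.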

How the results depend on the processing

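Alternatives that required 8 linker bases in every read or 5 at its end, allowed linker mismatches, matched the first 24 nt, exchanged the partner library, left out reads of mean quality under 20 for 10 over 2 dpp, allowed no mismatch or 1 genomic match for strand, thinned repeat reads, or took other denominators than those planned for a comparison (reads other than structural RNA and miRNA for the MILI-deficient and MIWI2-bound comparisons, repeat reads for all but the MIWI2-bound one) were chosen after seeing the data; the others were fixed before the data were examined. For the 14 values that answer the comparisons, 35 of 141 alternative values lay within the counting interval, 106 moved and none turned, and the cause was not tested. Over lists and named units, 754 of 1773 alternative values lay within the interval, 993 moved and 26 turned in direction. Of 97 log2 ratios of at least 2-fold, 59 stayed so in every alternative run and 12 turned in at least 1, while 31 of 69 smaller ratios reached 2-fold in at least 1.

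The reported values were a mean MIWI2-bound length of 28.2 nt, 84.5% 5′ U at 10 dpp, 65.6% A at position 10 of MIWI2-bound reads without 5′ U, 18.1% exon reads at 10 dpp, log2 ratios of -1.46 (piRNA-type reads, MILI-deficient over heterozygous), 1.72 (IAP, 10 over 2 dpp), -0.92 (B1, 10 over 2 dpp), 1.25 (ETn/MusD, MIWI2-bound over labelled 10 dpp MILI-bound), -2.65 (exon reads, labelled 10 dpp MILI-bound over 10 dpp total) and -1.77 (exon reads, labelled ovary total over 10 dpp total), L1 antisense shares of 52.9% (MIWI2-bound) and 7.15% (labelled ovary total), an overlap ratio of 1.56 and 7.63% shared sequences; alternatives are given in this order.

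Without sequences read in a single copy, values were 28.1613 nt, 89.2%, 72.2%, 13.9%, -1.84, B1 -1.29, ETn/MusD 1.74, exon -4.56 and -4.05, L1 antisense 52.5% and 0.858%, overlaps 2.52 and sharing 16.1%. Without the 10 most abundant they were 28.158 nt, 84.2%, 66.5%, 18.4%, -1.06, IAP 1.64, B1 -0.80, ETn/MusD 1.14, exon -2.56, overlaps 1.55 and sharing 7.001%. Over distinct sequences they were 79.0%, 62.0%, 24.2%, -0.50, IAP 0.59, B1 -0.47, ETn/MusD 0.84, exon -2.43 and -2.02, L1 antisense 53.7% and 10.3%, and overlaps 1.48. With inserts of 24 to 30 nt they were 28.0571 nt, 65.8%, ETn/MusD 1.19, exon -2.58 and overlaps 1.56362. From 18 nt they were 28.1128 nt, 84.1%, 65.3%, 17.9%, -1.63, ETn/MusD 1.45, exon -2.82 and -1.98, L1 antisense 9.07% in the labelled ovary, and sharing 8.09%. Depth was not matched where distinct sequences were counted or single copies were left out.

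The mean length was 28.0762 nt with 6 linker bases, 28.2107 nt with 10 and 28.1581 nt at a mean quality of 20 or more, where IAP was 1.69 and B1 -0.44 (10 over 2 dpp). With 8 linker bases in every read, values were 27.2947 nt, 84.5358%, 62.5%, 18.3%, B1 -0.94, ETn/MusD 1.37 and exon -2.21. With 5 at the end they were 28.1368 nt, -3.50, ETn/MusD 1.202 and exon -2.58. With linker mismatches they were 28.0805 nt, 84.9752%, 17.9%, IAP 1.68, B1 -1.07, ETn/MusD 1.30, L1 antisense 58.0% and 8.03%, overlaps 1.47 and sharing 8.02%. With the first 24 nt they were 85.1%, 66.1%, 17.8%, -3.05, IAP 1.57, B1 -1.16, ETn/MusD 1.38, exon -2.78, L1 antisense 59.1% and 9.39%, overlaps 1.46 and sharing 19.4%.

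The piRNA-type ratio was -8.96 per miRNA read, -5.58 per structural RNA read and -1.65 over annotated reads. Over reads other than structural RNA and miRNA, IAP was 1.70, B1 -0.94, ETn/MusD 0.97 and labelled MILI-bound exon -2.37; over repeat reads, IAP was 1.37, B1 -1.27 and ETn/MusD 0.68. ETn/MusD was 1.49 against the library labelled ovary total, and the exon ratios were -3.04 and -2.15 against 2 dpp. MIWI2-bound L1 antisense was 54.8% without mismatches, overlaps were 1.58 over all reads other than structural RNA and miRNA and 3.21 when thinned, and sharing was 8.22% at 100000 reads.

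Directions that turned were those of IAP over distinct sequences, to 0.55 (MILI-deficient over heterozygous), 0.23 (labelled 10 dpp MILI-bound over 10 dpp total) and 0.56 (labelled ovary total over 10 dpp total), and of IAPEz-int in the first of these, to 0.69. Depth was not matched for distinct sequences, so these turns also depend on it. In the MILI-deficient comparison, ratios per miRNA and per structural RNA read turned to -3.77 and -0.38 for RLTR10-int, -4.25 and -0.86 for RLTR10, -5.76 and -2.38 for MTA_Mm, -5.63 and -2.24 for MuRRS-int, -6.30 and -2.91 for L1_Mus2, -5.67 and -2.28 for Rps3, -5.76 and -2.37 for Rps12, and -6.07 and -2.68 for Sfmbt2, since these denominators are larger in the deficient library. With 5 linker bases at the end, MTA_Mm turned to -0.037, MuRRS-int to -0.81 and L1_Mus2 to -1.13, and with the first 24 nt MTA_Mm turned to -0.37, L1_Mus2 to -0.60 and Sfmbt2 to -0.41; the cause was not tested.

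Placing repeats first and sharing a sequence among its classes were not run, since each listed sequence carries 1 annotation. Strand for families of at least 1000 reads or for reads of a single family was not run, nor was the comparison of Dnmt3L-deficient testis. The quality filter was run for the mean length and for 10 over 2 dpp only. Requiring 8 linker bases gave no value for the MILI-deficient library. No paired analysis was possible because the labels pair no samples, and no library was left out because each group has 1. Depth limited the MILI-deficient library and the library labelled ovary total, where a count of 0 allowed 36.7 and 33.8 reads per 1000000.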

Other observations

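Small RNAs of gene exons ran mostly in the sense direction, with antisense shares of 2.42% at 2 dpp, 3.06% at 10 dpp, 5.67% in the MILI-deficient library, 12.5% in the library labelled ovary total, 15.6% in the library labelled 10 dpp MILI-bound and 22.8% in the MIWI2-bound library. Of 51 named genes with at least 100 exon reads at 10 dpp, at least 50% of them placed and some of them sense, 40 had the largest part of their sense reads in the 3′ untranslated region and 11 in the coding sequence. In the first group, 98.4% of sense reads of Cbx5, 96.1% of those of Tmed8 and 88.4% of those of Hic2 lay in the 3′ untranslated region. In the second, the coding sequence held 100% of those of Rps12, 98.6% of Nrros, 97.7% of Adsl, 87.2% of Foxc2, 80.4% of Rps3, 54.8% of Abhd2 and 55.3% of Fth1, which had 43.6% in the 5′ untranslated region. The test of whether exon small RNAs come from 3′ untranslated regions was fixed before its result was seen. Such regions held 61.3% of sense exon reads at 10 dpp against 56.9% by their length, a ratio of 1.08 (interval 1.07 to 1.08), which lay between the bounds set for either outcome and so did not decide it. The ratio was 1.203 at 2 dpp, 0.927 in the MIWI2-bound library and 0.633 in the MILI-deficient library. It was 0.911 in the library labelled 10 dpp MILI-bound and 0.842 in the library labelled ovary total.

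Marker miRNAs of 24 to 33 nt were counted for the lists fixed before the data were examined. Counts of a list are not counts of the cells it is named for. The primordial germ cell and pluripotent list had 24 reads in the MIWI2-bound library, 232 at 2 dpp, 392 at 10 dpp, 1856 in the MILI-deficient library, 7931 in the library labelled 10 dpp MILI-bound and 15 in the library labelled ovary total. All miRNA reads numbered 815, 957, 1388, 13148, 54776 and 188 in that order, so the counts of a list do not rank the libraries. In the same order, the gonadal soma list had 3, 12, 11, 426, 3861 and 10 reads. Blood miRNAs were 27.4%, 0.104%, 0%, 0.487%, 12.9% and 9.57% of all miRNA reads, and mir-451 gave all of those in the MIWI2-bound library. The meiotic germ cell list had 13 reads in the MILI-deficient library, 31 in the library labelled 10 dpp MILI-bound and 0 in the others. The muscle, liver, brain and endothelium lists had at most 2 reads of 24 to 33 nt in any library. Reads of 15 to 23 nt held more of them, with endothelium at 390 in the library labelled ovary total, 207 in the library labelled 10 dpp MILI-bound and 75 in the MILI-deficient library, and muscle at 64, brain at 35 and liver at 12 in the library labelled 10 dpp MILI-bound, which had most of these 3. At that length blood miRNAs were 3.52% of miRNA reads in the library labelled 10 dpp MILI-bound and 3.46% in the library labelled ovary total, and the gonadal soma list had 42802 and 4211 reads, the meiotic list 989 and 13, and the primordial germ cell and pluripotent list 20231 and 918.

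Exon reads matched by their first 24 nt for 10 ovary and oocyte genes numbered 3, 2, 0, 4, 2 and 2 in that order of libraries (1.32, 1.02, 0, 5.25, 1.17 and 3.07 per 1000000 reads), and those of 10 fetal testis genes 44, 15, 29, 28, 16 and 9 (19.4, 7.65, 12.8, 36.8, 9.35 and 13.8 per 1000000 reads), both lists chosen after the data were seen. Nanos2 stood at 250.7 per 1000000 reads in the MIWI2-bound library, 133.8 in the library labelled 10 dpp MILI-bound, 130.4 in the library labelled ovary total and 9.70 or less in the other 3. Dnmt3l had 20 reads in the library labelled 10 dpp MILI-bound and 7 or fewer in each other library.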
